A study of Oryza sativa with 2 samples.

How the data were processed

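Gene expression was measured in RNA from rice root hairs on 2 one-colour microarrays, which form 1 group labelled "07g39940 over" with replicates 1 and 2, called sample 1 and sample 2 here. Per the labels' protocols, sterilised seeds were kept on MSO medium for 3 days, the detached seminal roots were frozen in liquid nitrogen and rubbed so that the hairs came off, and total RNA was extracted with TRIzol and cleaned on a plant RNA column. The RNA was turned into Cy3-labelled complementary RNA with a low-input Agilent kit, per the labels. The cultivar label reads Don-gin. The labels do not say whether samples 1 and 2 are 2 transgenic lines, 2 batches of plants or repeats of one preparation, nor what "over" stands for, and the series as used here has no control group. No change caused by the titled locus was therefore tested.

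Each array was read out by Agilent Feature Extraction, version 11.5.1.1 per the file headers, while the submitters' processing notes name version 9.1. The intensity used here is the processed Cy3 signal, which the software had background-subtracted and detrended within each array, per the file headers, and which is not normalized between arrays. Per the file headers the probe design refers to the IRGSP5 rice build. A table of the whole series holds 1 column of log2 values per array and a present or absent call per spot, both deposited by the authors. How that table was made is not given in the sources used here. Set against the scanner values, its log2 columns followed the log2 median spot signal without background subtraction (r across spots 0.9995 for sample 1 and 0.9999 for sample 2). Their sorted values differed by at most 0.06, as quantile normalization leaves them. The column medians were 8.19 for both arrays.

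Each array held 45151 spots, of which 1417 scanner controls and 590 spots of named control probes were left out. A further 1436 spots with an outlier flag on either array were left out. The log2 processed signal of each array was scaled by subtracting the 75th percentile of that array, spots of one probe were averaged, and probes were assigned to loci by the systematic name in the files. This gave 34680 probes for 23303 loci. A probe counted as detected when the software called it well above background, and a locus as detected in both samples when at least 1 of its probes was so called on both arrays. The difference between the arrays is always sample 2 minus sample 1, averaged over the probes of a locus that were detected on both arrays, and folds are taken from these scaled values. Signals quoted for a locus are geometric means over the same probes, in arbitrary units. Levels of different probes were ranked against each other only to choose which detected members of a list to name. For a locus not well above background in one sample, the fold is given as "at least", taken against the higher of its own signal and the lowest signal among detected probes there. The array number limits the precision: the only spread available is that between the 2 arrays, and it may be technical.

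On both arrays together, the checks for a batch found 1 slide and 1 scan. No spot was saturated. Negative control spots had a median signal of 1.81 in sample 1 and 1.74 in sample 2, and the lowest signal called well above background was 7.33 and 7.14.

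The files hold locus identifiers and no gene descriptions or symbols. The reference table of RefSeq genes used here (assembly ASM3414082v1) does not list these identifiers, and none of the 1050 spots with a RefSeq accession matched it (0 matches). Gene lists were therefore built from locus identifiers known from rice gene nomenclature. The topics of the lists were fixed before the data were examined, as were the 24 members of 5 lists. A further 153 members, those of the other 14 lists and CASP1 among the stele and endodermis markers, were added after the files had been opened and before the values of these loci were looked at. CSLD1, Os05g0528000 and Os01g0856500, which also stand in added lists, had been seen as members of the root hair growth list. As a check of the names, 155 of 209 listed symbols occurred in the reference table. Of these, 134 lay on the chromosome that the locus identifier names and were found there once, and 131 were also in the same order along it. Symbols are printed only for these loci, and other members appear by locus identifier under their list's name. This check cannot exclude a wrong pairing of a symbol with a locus. Coordinates were not used, because the builds differ. Lists defined by descriptions (peroxidases, actin regulators, xyloglucan enzymes, ribosomal proteins, proteasome, laccases) were not analysed here. The locus in the sample titles uses a numbering that occurs 0 times among the probe and systematic names, so its level was not analysed here.

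The share of each list detected on both arrays was compared with that of all other loci by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 19 lists. These tests run across genes, which are not replicates. Differences between the arrays have 1 array on each side, so no p-value was computed for them. The median difference of each list was placed among those of 10000 random lists of the same size matched on mean signal by deciles, and called outside the random range below the 2.5th or above the 97.5th percentile. The genes named follow a rule fixed beforehand: the probes of the titled locus, per list up to 3 detected members with the highest mean signal and the first undetected one, with members listed beforehand first, and the 10 loci with a checked name that were furthest apart in each direction with all detected probes on one side. Signals quoted to show detection are therefore mostly those of the brightest members and are not typical of a list. One gene that this rule selects is not reported here. At most 2 loci outside the lists are named per direction, chosen after their values were seen. Also chosen after their values were seen were further members not well above background in both samples, photosynthesis loci with small or disagreeing differences, members of the lists used only in the additional observations, and the microRNA probes.

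Alternatives covered the background correction (normexp with an offset of 50 in limma 3.58.1 under R 4.3.3), quantile, median and loess scaling (span 0.3), the authors' table, the detection call, outlier flags, the handling of several probes, dim and saturated probes, and each sample alone. Further alternatives were added after the data were seen: the authors' present call, a threshold at the highest random-sequence or artificial control probe (signals 44.2 and 50.1), and the locus in the probe name, which differed from the systematic name for 1358 spots. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The procedure was tested on simulated data built on the 19553 loci detected on both arrays. Of 200 loci given a 4-fold or a 2.8-fold difference, 100% were recovered at each size, 0 unchanged loci passed 2-fold, and 6.25% of 400 unchanged lists fell outside the random range, where 5% would by definition. Of 20 shifted lists and of 20 lists with low detection, 100% were found, and 0% of 100 lists at the base rate of detection were called. These simulated lists held more loci than most of the real lists. The 100% therefore does not show that a short list would be found, and a short real list without a difference decides little. In the simulated differences every locus had the same noise, whatever its signal. The SD of that noise was smaller than the SD between the real arrays (0.44, and 0.58 in the dimmer probes). The recovery and the 0 false calls were thus largely fixed by this setting and do not carry over to dim loci.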

Results

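The series set out to list genes expressed in rice root hairs, the tubular outgrowths of root epidermal cells that take up water and nutrients, and its samples are titled after 1 locus, 07g39940. The only group consisted of 2 arrays of root hair RNA from 3-day-old seedlings (n = 2). Of 43144 spots that were not controls, 35884 (83.2%) were well above background in sample 1 and 36663 (85.0%) in sample 2. The 75th percentile of the signal was 2725 in sample 1 and 2772 in sample 2. With 1 group and no control, the files allow a description of what was detected and of how far the 2 samples differed.

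Genes known to be needed for root hair growth in rice were detected in both samples, for 6 of the 6 members on the array. Detection alone says little about a list, since 83.9% of all loci on the array were detected in both samples. CSLD1 (Os10g0578200), a cellulose synthase-like protein required for hair elongation, had a signal of 46042 in sample 1 and 51117 in sample 2. XXT1 (Os03g0300000), a xylosyltransferase of xyloglucan synthesis, gave 48800 and 47716. The locus Os10g0122600 of the same list gave 148676 and 128816, and Os05g0528000, also a member of the NADPH oxidase list, gave 14139 and 13972. Among the basic helix-loop-helix factors of the root hair family, 1 of 2 loci on the array was detected in both samples. That locus, Os01g0111500, had signals of 98.8 and 205, while Os02g0710300 was well above background only in sample 2.

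Most loci of wall growth and tip growth were likewise detected, as were most loci on the array (83.9%). All 5 cellulose synthases of the primary wall were well above background in both samples, with CESA1 at 28457 and 26038, CESA3 at 60249 and 55685, and CESA5 at 20845 and 21339. In the CSLD family 3 of 4 loci were detected, among them CSLD4 (2881 and 3332) and CSLD2 (2226 and 2271), and CSLD5 was not. All 7 RAC/ROP GTPases, switches of polar cell growth, were detected, with RAC6 at 22137 and 21370 and RAC3 at 1611 and 1665. Of 7 NADPH oxidase loci 6 were detected, including Os01g0835500 at 28301 and 27488, and Os05g0465800 was not. Expansins, which loosen cell walls, were detected at 16 of 17 loci. EXPA3 had signals of 1947 and 3042 and EXPA8 of 831 and 1182, and EXPA32 was not well above background.

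Uptake systems were detected at 77.8% (phosphate) to 88.9% (nitrogen) of their loci, around the 83.9% of all loci on the array. Of 17 aquaporins 15 were detected, with TIP2;2 at 283091 and 263273, TIP1;1 at 281172 and 275421, and PIP2;1 at 17879 and 19390. PIP2;8 was not well above background in either sample, and PIP2;7 only in sample 2, with close mean signals over its probes (3.99 and 4.33). Nitrogen transporters were detected at 8 of 9 loci, among them the ammonium transporters AMT1;1 (33492 and 31698) and AMT2;1 (11861 and 13646). NRT2.1 was the exception, and its near-identical copy NRT2.2 was detected (2848 and 2732), so probes for this pair were not taken to separate the genes. Phosphate transporters were detected at 7 of 9 loci, with PT2 at 19906 and 23793, PT8 at 4123 and 4907 and PT3 at 3065 and 4497. PT11 and PT7 were not. Potassium transport was detected at 4 of 5 loci, with the transporter HAK1 at 31205 and 34150 and the channel AKT1 at 4008 and 3954, and Os01g0756700 was not.

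Of hormone-related genes, all 6 ethylene synthesis loci were detected, with ACO1 at 187 and 268 and ACS2 at 174 and 217. Auxin transport loci were detected at 4 of 6, among them Os01g0856500 at 318 and 422. PIN9 was well above background only in sample 1 and Os01g0643300 only in sample 2. All 12 heat shock loci were detected, including Os08g0500700 at 85106 and 88929.

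Markers of cells that rubbing could bring along were mixed. Of 6 markers of the stele and endodermis, the inner root tissues, 2 were detected in both samples. These were PHO1;2 (132 and 110) and CASP1 (138 and 91.4), while SCR1, SCR2 and HKT1;5 were not well above background in either sample and SHR1 was so only in sample 2. Of the secondary wall cellulose synthases CESA4 (92.7 and 122) and CESA7 (65.2 and 77.3) were detected and CESA9 was not. All 11 cell cycle loci were detected, with PCNA at 592 and 702, CDKB1;1 at 280 and 321 and MCM3 at 160 and 181. All 23 photosynthesis loci were detected in both samples, and 6 of 11 seed storage and amylase loci. AMY3D, an alpha-amylase, was not detected in either sample.

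Over the whole array, 19553 of 23303 loci (83.9%) were well above background in both samples, 563 only in sample 2, 188 only in sample 1, 2998 in neither and 1 in each sample by different probes. No list differed from the remaining loci after adjustment (0 of 19 lists by two-sided Fisher's exact tests across genes), and 3 did at an unadjusted p under 0.05. The share was 33.3% for the stele and endodermis markers against 83.9% (exact p = 0.00763, adjusted p = 0.145) and 100% for photosynthesis loci against 83.9% (exact p = 0.0403, adjusted p = 0.255). For seed storage and amylase loci it was 54.5% against 83.9% (exact p = 0.0212, adjusted p = 0.202), and 90.9% in sample 1 alone. With the 5 stele and endodermis markers listed beforehand alone, 1 was detected (20%), and the adjusted p of the exact test over 5 lists was 0.0146. The detection call was lenient: 6 of 24 random-sequence and artificial control probes (25%) received it too, and above the highest of these 16175 loci (69.4%) remained detected and 10 of the 23 photosynthesis loci (43.5%). The loci named above as well above background in 1 sample only had mean signals over probes below that highest control probe (44.2 in sample 1, 50.1 in sample 2). Such a call is therefore no measure of a difference between the samples.

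**Figure D1:**
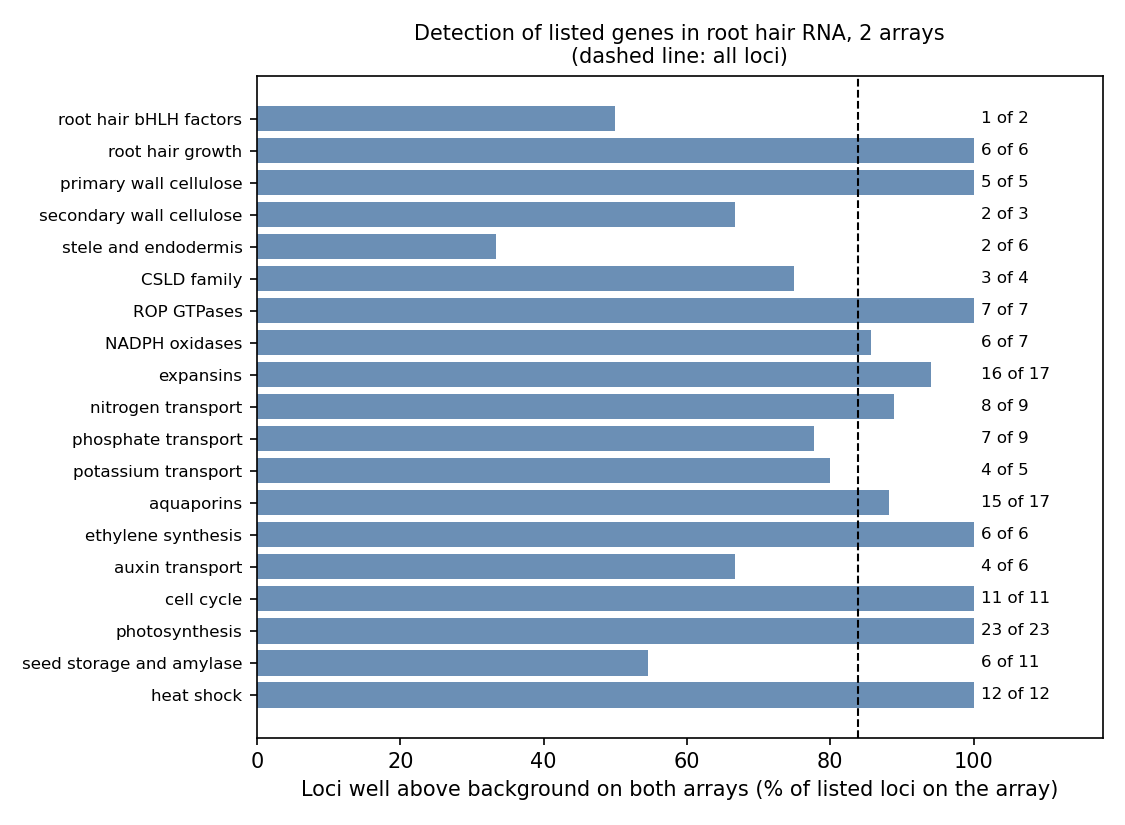
Share of the loci of each gene list on the array that were well above background on both arrays, in percent, with the counts at the right and the share of all loci (83.9%) as a dashed line. Stele and endodermis markers stand lowest at 2 of 6 loci. All loci were detected in 7 lists, among them root hair growth (6 of 6), cell cycle (11 of 11) and photosynthesis (23 of 23). No list differed from the remaining loci after adjustment.

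The 2 samples were then compared with each other, which is the only spread the design offers. Over 29408 probes detected on both arrays, signals correlated with Pearson's r = 0.992 and Spearman's rho = 0.993 across probes, which are not independent replicates. The SD of the log2 difference was 0.44, with 0.58 in the dimmer 50% of probes and 0.17 in the brighter 50%, and 97.1% of probes lay within 2-fold. Repeated spots of one probe had a median SD of 0.11 in sample 1 and 0.10 in sample 2 over 18 probes with at least 8 spots. These are SDs within an array, not of a difference between arrays, so the 2 SDs cannot be compared directly. For the same 18 probes, the scaled difference between the arrays was set against its standard error from the repeated spots. It lay beyond 2 standard errors for 7 probes (38.9%). Spots are not replicates of a sample, and an error of scaling would count here too. Where a locus had at least 2 detected probes (6297 loci), the differences of the first and second probe correlated across loci with r = 0.88 and rho = 0.72. Of 165 loci whose first probe was at least 2-fold apart, the second probe lay on the same side for 160 (97.0%).

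Among the 19553 loci detected in both samples, 453 were at least 2-fold apart. Of these 358 (79.0%) were higher in sample 2 and 95 higher in sample 1. At 8-fold the balance was the other way, with 30 loci higher in sample 1 and 8 higher in sample 2. The count and the split moved with the setting. Normexp background correction left 113 loci, 62.8% of them higher in sample 2, the authors' deposited table gave 142 (60.6%), quantile normalization 351 (63.0%), loess 383 (70.2%) and median scaling 390 (72.3%). Without the filter on dim probes 1174 loci were 2-fold apart (72.2% higher in sample 2). Outside the gene lists, the loci furthest apart toward sample 1 were Os07g0219250 (115-fold, signals 3560 and 31.6) and Os01g0944700 (104-fold, 1004 and 9.86). Toward sample 2 they were Os01g0251400 (15.1-fold, 17.3 and 266) and Os10g0150800 (14.2-fold, 18.0 and 260). The lower signal of each did not exceed that of the highest random-sequence or artificial control probe in that sample (44.2 in sample 1, 50.1 in sample 2), so these folds are imprecise.

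**Figure D2:**
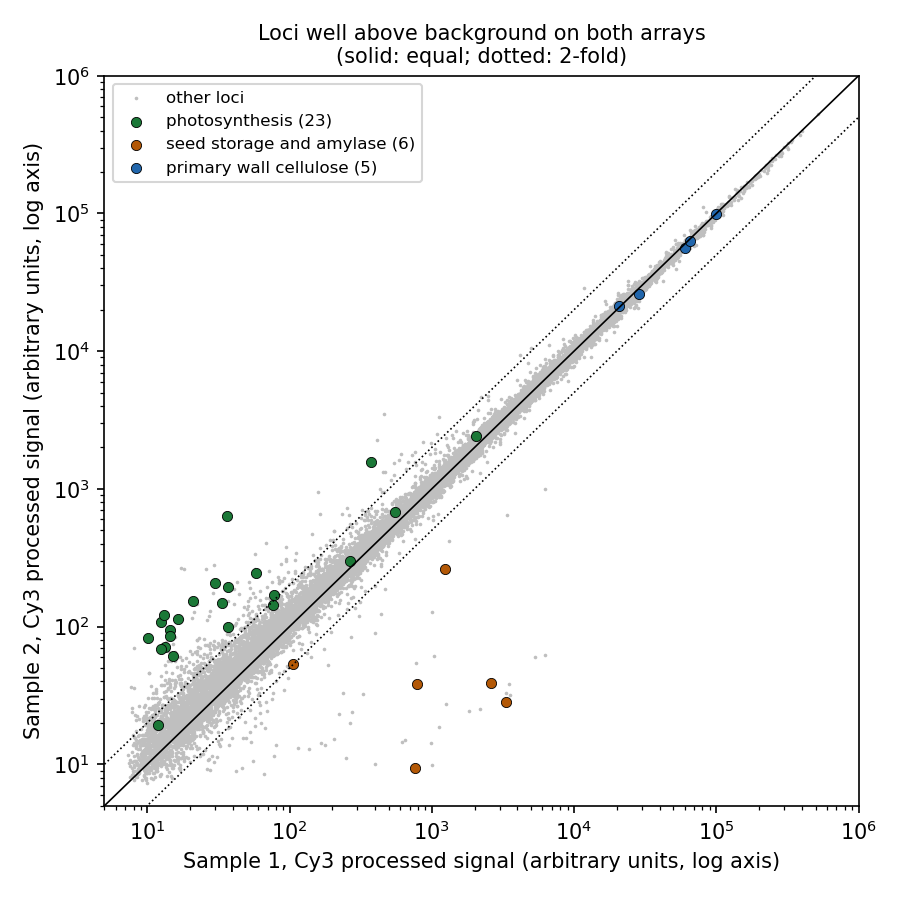
Processed Cy3 signal of each locus detected on both arrays in sample 1 (x axis) and sample 2 (y axis), both on log axes in arbitrary units, with photosynthesis, seed storage and amylase, and primary wall cellulose loci coloured, the line of equality solid and 2-fold lines dotted. The 23 photosynthesis loci lie above the line of equality, the 6 seed loci below it, and the 5 cellulose synthases close to it.

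Genes of seed storage proteins and starch breakdown were higher in sample 1. All 6 loci of that list detected in both samples were higher there, 5 of them at least 2-fold, and the median log2 difference was -5.23 (0th percentile of random lists). Among the loci with a checked name, glutelins, the main storage proteins of the rice grain, were furthest apart. Os02g0249800, a member of the list without a checked name, was further apart than any of these. Its signals were 3316 in sample 1 and 28.5 in sample 2 (log2 difference -6.89, SD 0.12 between 2 probes). GLUA3 (Os03g0427300) was 82.1-fold higher in sample 1 (signals 761 and 9.42, 1 probe), GLUA1 (Os01g0762500) 67.5-fold (2595 and 39.1, log2 SD 0.11 between 3 probes) and GLUA2 (Os10g0400200) 20.9-fold (786 and 38.3, log2 SD 0.39 between 4 probes). With normexp correction these log2 differences were -3.76 for GLUA3, -4.73 for GLUA1 and -3.14 for GLUA2. In sample 2 the mean signals over probes of 4 of the 6 loci did not exceed that of the highest random-sequence or artificial control probe (2 of 6 by the highest probe of each locus), against 0 in sample 1. Another 4 loci were well above background only in sample 1, among them GLUB4 (Os02g0268300), at least 75.3-fold higher, and GLUD1 (Os02g0249000), at least 56.0-fold higher. With these 4 at their bound the list's median was -5.87. Alpha-amylases, which break down starch at germination, differed less: AMY1A (Os02g0765600) was 4.89-fold higher in sample 1 and AMY3E (Os08g0473600) 1.99-fold. Glutelin genes have near-identical copies, which the probes were not taken to separate. Under normexp correction the median of the list was -3.45.

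Photosynthesis genes were higher in sample 2. All 23 loci were higher there, 18 of them at least 2-fold, with a median log2 difference of 2.36 (100th percentile of random lists). CAB2R (Os01g0600900), a light-harvesting chlorophyll-binding protein, was 17.4-fold higher (signals 36.1 and 637, log2 SD 0.02 between 2 probes). RCA (Os11g0707000), which activates Rubisco, was 6.41-fold higher (14.5 and 94.4, log2 SD 0.54 between 9 probes), and PSAH (Os05g0560000), a photosystem subunit, was also higher (10.2 and 82.7, log2 difference 3.00). Of the loci of the small subunit of Rubisco (RBCS), Os12g0292400 was 8.47-fold higher with 1 probe and Os12g0274700 3.99-fold with 7 probes. These families also have near-identical copies. Differences were smaller at Os11g0242800 (2055 and 2433), Os07g0141400 (552 and 680) and Os07g0544800 (265 and 298). Probes disagreed in direction at Os03g0592500 (5 probes, log2 difference 2.05, SD 2.01) and at Os12g0420400 (5 probes, log2 difference 1.39, SD 1.11). In sample 1 the mean signals over probes of 16 of the 23 loci did not exceed that of the highest random-sequence or artificial control probe (13 by the highest probe of each locus), against 1 in sample 2. The median was 1.07 with normexp correction and 1.39 in the authors' deposited table, and with normexp CAB2R differed by 2.78 on the log2 scale, PSAH by 1.11 and RCA by 1.07, and the RBCS loci by 1.37 and 0.67. Of the 50 loci furthest toward sample 2, 15 belonged to this list, and of the 50 furthest toward sample 1, 5 were seed loci.

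Smaller shifts were seen in 4 other lists whose medians lay outside the random range. Expansins were higher in sample 2 at 13 of 16 loci (median log2 difference 0.35, 99.95th percentile). EXPA1 (Os04g0228400) was 3.61-fold higher there (52.4 and 192, log2 SD 0.02 between 2 probes), EXPA5 2.16-fold, EXPA7 1.96-fold and EXPA4 1.94-fold. With normexp correction the log2 differences were 1.15 for EXPA1, 0.61 for EXPA5 and 0.34 for EXPA7, and the signal of EXPA7 in sample 1 (24.4, against 48.7 in sample 2) did not exceed that of the highest control probe. Phosphate transporters were higher in sample 2 at 6 of 7 loci (median 0.23, 98.9th percentile), none of them by 2-fold. These shifts go in the same direction as the photosynthesis genes. The list named potassium transport had a median of -0.41 (0.01th percentile). That median rested on HAK5 (3.04-fold higher in sample 1, 57.0 and 19.1) and HKT2;1 (1.72-fold, 278 and 164, log2 SD 0.05 between 5 probes). HAK1 and AKT1 differed by 0.11 and -0.04, so the shift is not one of potassium transporters as a whole. With normexp correction HAK5 differed by -0.55 on the log2 scale, and its signal in sample 2 did not exceed that of the highest control probe. The median of the 2 detected stele and endodermis markers was -0.45 (1.62th percentile), with CASP1 1.53-fold and PHO1;2 1.22-fold higher in sample 1. Without the filter on dim probes the potassium and stele lists lay inside the random range (medians -0.04 and -0.11).

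The other 12 lists lay inside the random range. If loci were independent, 0.9 of the 18 lists compared would fall outside by chance, and 6 did. Members of a list are often related genes with near-identical copies, and some lists share loci. More than 0.9 may therefore fall outside by chance. Root hair growth genes had a median difference of 0.04 and primary wall cellulose synthases of -0.07. The medians were 0.13 for the CSLD family, 0.04 for RAC/ROP GTPases, -0.05 for NADPH oxidases, -0.07 for nitrogen transporters, 0.05 for aquaporins and 0.10 for heat shock loci. Median scaling, which moves all loci alike, put root hair growth, RAC/ROP and aquaporin loci at -0.05, -0.05 and -0.04, and quantile normalization put RAC/ROP loci at -0.03 and aquaporins at -0.0015. Single members still stood apart, such as RAC1 (Os01g0229400), 2.84-fold higher in sample 2 (17.2 and 49.5, log2 SD 0.02 between 2 probes). In sample 1 its signal did not exceed that of the highest control probe, and its log2 difference was 0.42 with normexp correction and 0.58 in the authors' table. Ethylene synthesis loci had a median of 0.21 and secondary wall cellulose synthases of 0.30. Cell cycle loci were higher in sample 2 at all 11 loci, with a median of 0.32 just inside the upper end of the random range (0.32). Auxin transport loci had a median of 0.39 (96.3th percentile).

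**Figure D3:**
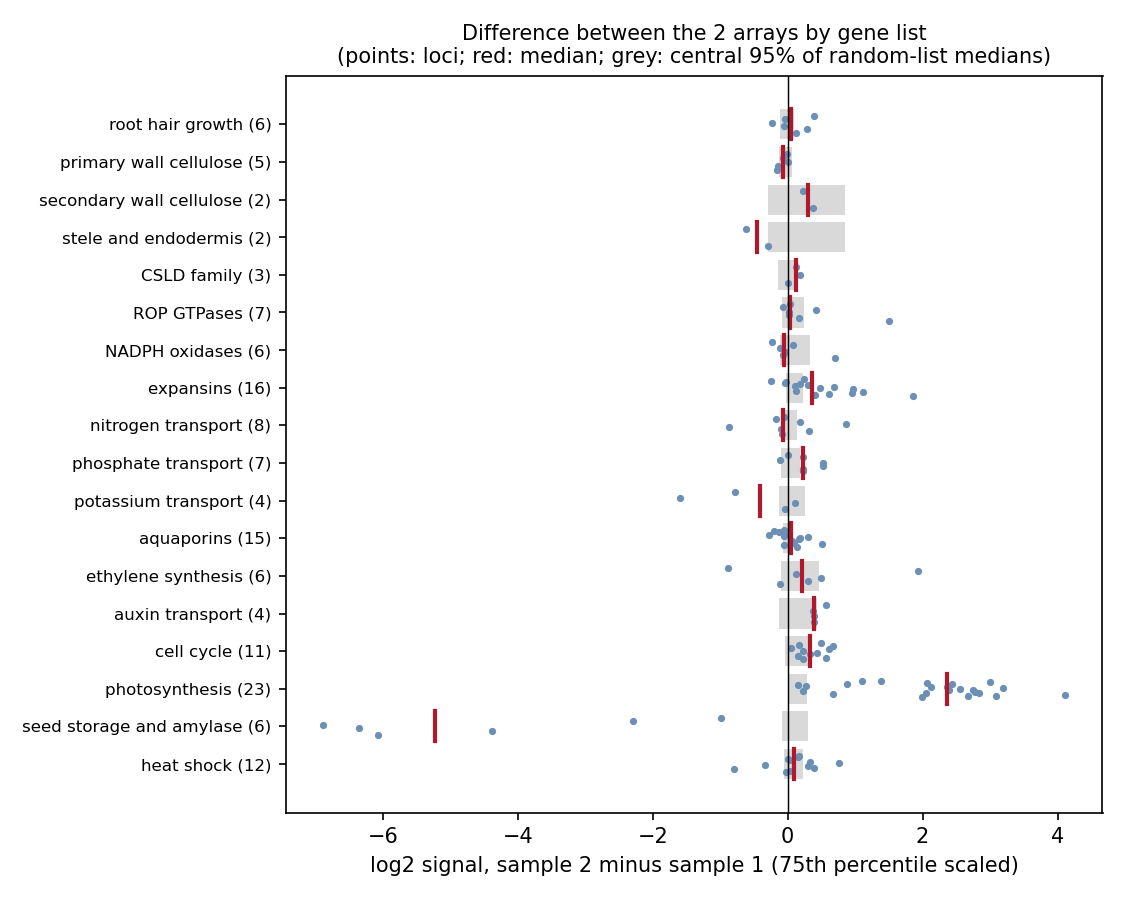
Log2 difference between the arrays, sample 2 minus sample 1 after scaling to the 75th percentile, for each locus detected on both arrays (points), by gene list with the number of loci in brackets. Red lines are list medians and grey bars the central 95% of medians of matched random lists; the seed list lies far to the left (-5.23) and photosynthesis to the right (2.36), with the root hair growth list at 0.04.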

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

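The test in this part was chosen after the result was seen. Random-sequence and artificial control probes, so named in the files, were called well above background on both arrays for 6 of 24 probes (25%), and a count of 0 would allow a share of up to 12.5%. By kind these were 5 of 12 random-sequence probes (41.7%) and 1 of 12 artificial ones (8.33%), with highest signals of 44.2 in sample 1 and 50.1 in sample 2. A candidate explanation is unspecific binding at signals just above background. If so, these probes would lie under the 25th percentile of the signals so called, and the highest of them lay at the 15.3th percentile of detected locus probes, which goes with that explanation. The call alone then does not separate weak expression from such binding, and no biological explanation was tested.

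Probes for microRNAs and their flanking sequences, which entered none of the comparisons, were well above background on both arrays for 270 of 510 probes (52.9%), more often than the control probes (two-sided Fisher's exact test across probes, p = 0.0107). The share was 44.7% for mature sequences (p = 0.0793 by the same exact test) and 57.1% each for the 5' and 3' flanking probes (p = 0.00406). The 3' probe of osa-miR168a had signals of 35146 in sample 1 and 35315 in sample 2. The 3' probe of osa-miR528 was higher in sample 1 (16749 and 11389, log2 difference -0.58), and its 5' probe differed alike (log2 difference -0.62).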

How the results depend on the processing

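No paired analysis was possible because the series has 1 group and therefore no pair of groups that share replicate numbers. The level of the titled locus and the lists defined by descriptions were not run under any setting, and leaving out saturated probes removed none (0 saturated spots), so that setting tests nothing. Each sample alone gave 19742 to 20117 detected loci, and the other detection settings kept the count within 1.5 times of the main one. With the members listed beforehand alone, 1 of 5 lists passed the adjusted threshold, the stele and endodermis markers, and under the other 9 settings 0 lists did.

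Normexp correction compresses low signals by construction, through its offset of 50. The authors' table followed spot signals without background subtraction, which compresses low signals too, and its values also looked quantile-normalized. These effects were not told apart. Normexp gave r = 0.995 between the arrays, 113 loci 2-fold apart, r = 0.894 between probes of a locus, and list medians of 1.07 for photosynthesis and -3.45 for seed loci. The authors' table gave r = 0.994, 142 loci, r = 0.886, and medians of 1.39 and -4.05. Quantile normalization gave r = 0.864 between probes and medians of 2.17 and -5.36. Median scaling put photosynthesis at 2.26, and loess at 2.25 with r = 0.872 between probes. The probe with the highest mean signal gave 1.98 and -5.44. Without the filter on dim probes the arrays correlated with r = 0.991, 1174 loci were 2-fold apart, probes of a locus correlated with r = 0.720 and the seed median was -6.08. Loci from the probe names gave r = 0.874 between probes and a seed median of -6.08, and keeping outlier spots gave r = 0.874. Median scaling moves all loci alike and, like leaving out saturated probes, cannot change a list's place among random lists. Under the other 9 settings, the main one included, the seed and photosynthesis lists lay outside the random range, as did expansins (0.24 to 0.37) and phosphate transporters (0.16 to 0.23). The potassium transport list and the stele and endodermis markers did under 8 of 9. Cell cycle loci lay outside under 6 settings, auxin transport under 5, the CSLD family under 4 and nitrogen transport under 2, none of them in the main one. The cause of the remaining movements was not tested. Settings on probe pairs, the authors' present call, the control-probe threshold and the probe names were added after the data were seen. No scaling moved the median of all loci by over 0.1 (-0.06 with median scaling). Signal over background limits the comparison of dim probes: the SD between the arrays was 0.58 in the dimmer probes and 0.17 in the brighter ones.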

Other observations

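Tests of spot noise, of normalization and of medians with loci at their bound in this part were chosen after the results were seen, and the bound for spot noise was moved from 90% of probes to an interval above 50% after its values were known. Under the first bound the test of photosynthesis loci would have been undecided. The other 4 lists tested here were written after the list differences were seen and before their own values were. Genes of the endosperm, the storage tissue of the grain, most but not all of them for starch synthesis, were close between the samples. Of these, 5 of 8 loci were higher in sample 1 and none 2-fold, and Os06g0229800 was well above background only in sample 1. GBSSI (Os06g0133000), which makes amylose, had signals of 1989 in sample 1 and 1652 in sample 2, and AGPS2 (Os08g0345800), which makes the sugar donor of starch, 1185 and 1168. Of genes for chlorophyll synthesis and carbon fixation, 4 of 9 loci were at least 2-fold higher in sample 2. One of these was CHLH (Os03g0323200), a subunit of magnesium chelatase (18.1 and 49.3, log2 SD 0.98 between 2 probes), while GLO1 (Os03g0786100), a glycolate oxidase, was close (25.7 and 29.0). Loci with the largest excess in sample 1 lay together in the genome more than random loci did. Of the 30 loci at least 8-fold higher there, 14 had another of them within 5000 of the number in the locus identifier, which runs along the chromosome. The median was 2 and the highest value 12 over 10000 random draws of 30 loci. These draws did not allow for neighbouring copies of one gene, whose probes can share signal, so the neighbours are not independent. Only 4 of the 30 are in the lists used here. Without gene descriptions, whether the others are also seed genes was not tested. Of the 8 loci at least 8-fold higher in sample 2, 0 had such a neighbour.

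Seed storage loci were higher in sample 1, by a median log2 difference of -5.23. Spot noise is argued against by 18 of the 19 probes of the list detected in sample 1 (94.7%, exact interval 74.0% to 99.9%). These were at least 2-fold higher there, against 0.948% of all probes detected there. The 19 probes belong to 10 loci, so they are not independent and the interval is too narrow. Normalization is argued against as well, since the median stayed at -3.45 or lower under the 4 scalings run that do not move all loci alike. Whole-seed RNA stays open. Embryo and aleurone genes had a median of 0.27 toward sample 2 (4 of 5 loci), inside the random range (87.7th percentile). A median at or above 0 had been set as the bound against it. Matched random lists had a median above 0 too (0.10, central 95% from -0.12 to 0.44), so that bound was too lenient to exclude it. RNA carried over from the endosperm may contribute and stays open as well. The endosperm genes shifted by -0.062 (2.72th percentile, inside the random range). With Os06g0229800 at its bound they shifted by -0.078 (1.56th percentile of random lists with such loci at their bound), which goes with such carry-over. That move rested on this 1 locus, so it decides nothing. Its signal in sample 1 (14.3) did not exceed that of the highest random-sequence or artificial control probe there (44.2). Signals that both samples shared would also hide a small share. A difference between 2 plant lines stays open too, since the labels do not define the samples.

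Photosynthesis loci were higher in sample 2, by a median log2 difference of 2.36. Spot noise is argued against by 107 of the 124 probes of the list detected in sample 2 (86.3%, exact interval 79.0% to 91.8%). These were at least 2-fold higher there, against 3.83% of all probes detected there. The 124 probes belong to 23 loci, so they are not independent and the interval is too narrow. Normalization is argued against by a median of 1.07 or more under the 4 scalings run that do not move all loci alike. RNA of green tissue, or roots that greened more in sample 2, may be the source and stays open. Chlorophyll and carbon fixation genes had a median of 0.23 inside the random range (95.6th percentile), with 4 loci at least 2-fold higher in sample 2 and 2 loci higher in sample 1, and the signals of 4 of the 9 loci in sample 1 and of 3 in sample 2 did not exceed that of the highest control probe as means over probes. Os04g0234600 was well above background only in sample 2 (at least 3.02-fold higher), and with it at its bound the median was 0.73 (99.99th percentile of such random lists), which goes with this source. The outcome thus turned on 1 locus, so it decides nothing. The mean signal of Os04g0234600 over its probes in sample 2 (11.4) did not exceed that of the highest control probe there (50.1). Shoot tissue is also open: 5 of 6 shoot identity genes were well above background in sample 2, but 4 of these 5 did not exceed the highest random-sequence or artificial control probe there by their own highest probe, and 2 of them were measured in both samples (median 0.14). The other 3 were so only in sample 2, YAB1 at least 1.82-fold, YAB2 at least 1.98-fold and YAB5 at least 1.38-fold higher, and with these at their bound the median was 0.47 (85.8th percentile). A biological difference between the samples was not tested because the labels name none.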
